A study of Populus davidiana with 6 samples.

How the data were processed

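Leaf RNA of Populus davidiana, an aspen, was measured by RNA sequencing in 6 libraries of the cultivar Seogwang9, which the labels call drought tolerant. The plants came from internode culture and were about 6 weeks old, per the labels' protocols. In the treated group the plants were lifted from the medium, washed and kept in open air for about 10 minutes; 3 libraries were controls and 3 came from air-dried plants. Whether the controls were also lifted and washed, and whether the 3 leaf samples of a group came from separate plants, is not given in the sources used here. The p-values therefore measure the spread between these samples, which may be technical. Libraries were made from poly(A) RNA with a TruSeq kit and read as 100 bp pairs on a HiSeq-2500, per the labels' protocols. FastQC, TopHat and Cufflinks are named in the submitters' processing notes, without versions. The genome build and any strand setting are not given in the sources used here, so coordinates are printed as deposited. Accessions that start with POPTR are those of Populus trichocarpa, so the reference was probably that species and not Populus davidiana. Chromosomes, spans, gene order and known transcripts are those of the reference and may differ in Populus davidiana. Whether reads that differ from the reference were lost, which would lower some values, was not tested.

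The deposited values were FPKM (fragments counted per transcript, scaled by transcript length and by library size), 1 value per transcript and library, per the file headers. Each library listed the same 112919 transcripts, of which 45773 were marked known and 67146 were marked as assembled from the reads, and these belonged to 40537 genes. For 2158 genes no transcript was marked known. The gene name column was empty throughout, and the accessions were not paired with names or functions by any table used here. For that reason none of the 31 functional gene lists fixed before the data were examined could be applied, and genes are given by accession or coordinates.

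The FPKM of all transcripts of a gene were summed. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, which left 22356 genes, 21653 of them on chromosomes 1 to 19. Values were used as deposited, without rescaling, as log2(FPKM + 1). Groups were compared with limma 3.58.1 (lmFit and eBayes with a trend on the mean level) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The procedure was tested on simulated data with 22356 genes and 3 libraries per group. It recovered 88% of 50 genes planted at a log2 change of -2, 58% of 50 at -1, 64% of 50 at 1 and 90% of 50 at 2. Beside these 44, 29, 32 and 45 genes, 12 unchanged genes were called. The planted genes were a much smaller share than the 13.04% called in the data, and the simulated values held no structure but the groups. These rates therefore need not hold for the data.

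The number of reads per library is not given in the sources used here. FPKM of low genes moved in steps, and ratios of these steps between libraries gave depths relative to control 1 of 1.016 for control 2, 1.334 for control 3, 0.892 for air-dried 1, 1.06 for air-dried 2 and 0.957 for air-dried 3. Absolute depth remained unknown, so no counting interval or detection limit is given. Very short loci had extreme FPKM: 419 transcripts of up to 130 bp held between 37.8% and 70.0% of the summed FPKM of a library. An FPKM of 0 in these files can be a failed estimate, so genes at 0 in every library of a group are described as listed at 0, without a fold.

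The rule for genes given by accession, fixed before the data were examined, took the 8 largest rises and the 8 largest falls with names, or, where no names could be had, 2 accessions that rose and 2 that fell. The second part applied. Its ranking was read as the largest fold changes among genes past the threshold whose groups did not overlap, leaving out genes listed at 0 in every library of a group because no fold can be given for them. This reading was settled after the values were seen; with genes listed at 0 included, other loci would have ranked first.

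The libraries fell into 2 sets that crossed the groups. Set A held controls 1 and 2 with air-dried 1, and set B held control 3 with air-dried 2 and air-dried 3. The sets were found after seeing the data, from rank correlations of transcripts and from the steps of low values, and the labels name no batch. The set was then added as a term, and changes were also estimated within each set from a model that pooled the spread. Replicate numbers were not treated as pairing the libraries across groups.

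Counts of changed genes and the accessions above were planned. The comparisons by genomic span, chromosome, neighbouring position, known or assembled transcript, size of rises against falls and leading transcript were chosen after the data were examined. Fisher's exact test, two-sided, was used for shares of genes. Permutation tests used 100000 shuffles for the main values, 10000 for restricted groups of pairs or genes, and 1000 for the alternatives. For neighbours, calls were shuffled over the tested genes of each chromosome, with one-sided p-values; genes are not independent replicates in any of these tests. Alternatives tried were pseudocounts of 0.1 and 0.5, no filter on low values, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, a replicate block, eBayes without trend, single transcripts and each library left out in turn. The library set as a term, genes spanning at least 300 bp and sums of known transcripts were added after the data were examined. Position and permutation analyses used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures used matplotlib 3.10.9.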

Results

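The transcript levels of aspen leaves were compared between 3 control libraries and 3 libraries from plants exposed to open air for some 10 minutes. In the air-dried leaves 98060 to 98561 transcripts had an FPKM above 0, and in the controls 98441 to 99285. The median FPKM of the 22356 tested genes lay between 11.8 and 12.6 in the 6 libraries. Summed FPKM was 1767948, 3552549 and 3002168 in the controls and 1891656, 2136565 and 1672566 in the air-dried libraries. A single 100 bp locus on scaffold 71 (66137 to 66236) held 46.7% of the sum in control 2, with an FPKM of 1660000. Another 100 bp locus on chromosome 15 (4838242 to 4838341) held 54.3% in control 3, with 1630000. Each was listed at 0 in the other 5 libraries. Depth relative to control 1 ranged from 0.892 in air-dried 1 to 1.334 in control 3.

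The main comparison asked which leaf transcripts differ after the short drying treatment. Levels of 1253 genes rose and levels of 1663 genes fell in the air-dried leaves, together 13.04% of the genes tested. Most changes were moderate, with a median fold of 1.605 among rising genes and 1.578 among falling genes. Rises reached larger sizes: 356 rising genes (28.4%) changed at least 2-fold against 332 falling genes (19.96%), with an odds ratio of 1.59 (Fisher's exact test, p = 1.202e-07). On this scale a fall cannot exceed the control level of log2(FPKM + 1), while a rise has no such limit. Part of the difference may therefore come from the scale, and the shares were not compared at other pseudocounts. At least 4-fold changes were found in 87 rising and 36 falling genes, and at least 8-fold changes in 37 and 11. These size classes, on the log2(FPKM + 1) scale, include genes listed at 0 in every library of a group, for which no fold can be given; without them 351 rising and 325 falling genes changed at least 2-fold, 83 and 30 at least 4-fold, and 33 and 7 at least 8-fold. The calls came from limma with a Benjamini-Hochberg adjusted p under 0.05. At an unadjusted p under 0.05, 2816 genes were higher and 3237 lower. In 3558 genes all 3 air-dried values lay above all 3 control values and in 3762 genes they lay below, together 32.7% of genes where chance gives 10%. The median log2 change over all tested genes was 0.0080.

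**Figure D1:**
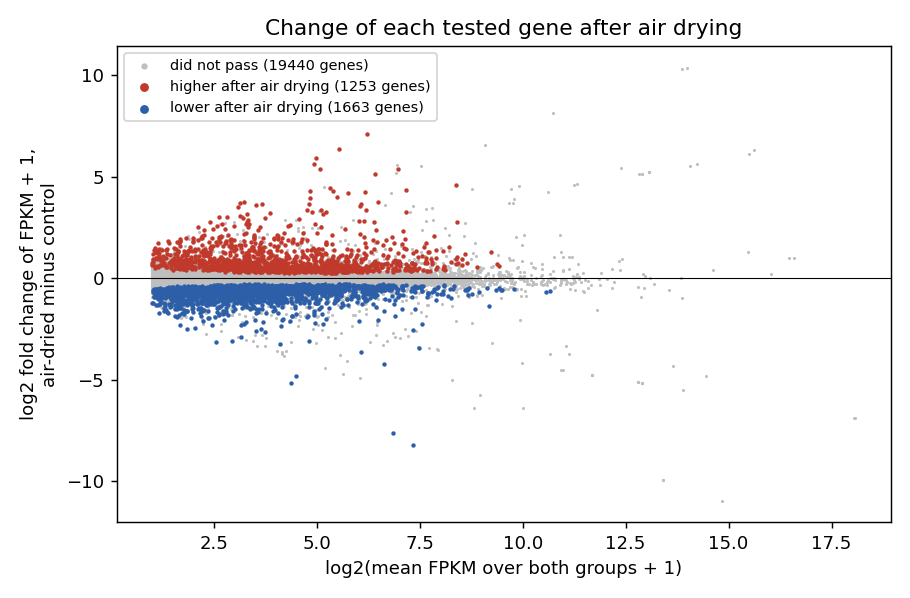
Each point is a tested gene, with the log2 of its mean FPKM over both groups plus 1 on the x axis and its log2 fold change of FPKM plus 1, air-dried minus control, on the y axis. The 1253 genes that rose (red) and the 1663 that fell (blue) lie at all but the highest levels, and several grey points far from 0 are loci that did not pass the test.

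The gene POPTR_0009s16050, on the plus strand of chromosome 9 (12284978 to 12286144), rose from 4.93 ± 0.581 FPKM (SD, n = 3) in the controls to 244 ± 14.9 FPKM (SD, n = 3) after drying. Its log2 fold change was 5.37 (SE 0.0956), with a limma adjusted p of 2.033e-05. POPTR_0018s08320, on the plus strand of chromosome 18 (9245946 to 9246542), rose from 0.626 ± 0.417 FPKM to 64.7 ± 6.95 FPKM (SD, n = 3 each), with a log2 fold change of 5.37 (SE 0.21) and a limma adjusted p of 0.0001416. Its control values lay below the pseudocount of 1, and its log2 fold change was 5.93 with a pseudocount of 0.5 and 6.70 with 0.1. The largest falls belonged to POPTR_0013s05400 and POPTR_0006s06430. POPTR_0013s05400, a 273 bp gene on the minus strand of chromosome 13 (3856552 to 3856824), fell from 186 ± 111 FPKM to 8.93 ± 5.32 FPKM (SD, n = 3 each). Its log2 fold change was -4.24 (SE 0.598), with a limma adjusted p of 0.008101. POPTR_0006s06430, on the plus strand of chromosome 6 (4590788 to 4592356), fell from 124 ± 8.27 FPKM to 9.10 ± 1.53 FPKM (SD, n = 3 each), with a log2 fold change of -3.64 (SE 0.123) and a limma adjusted p of 9.147e-05. Each of these 4 genes had 1 known transcript and overlapped no other listed gene; whether near-identical copies share their reads is not known here.

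**Figure D2:**
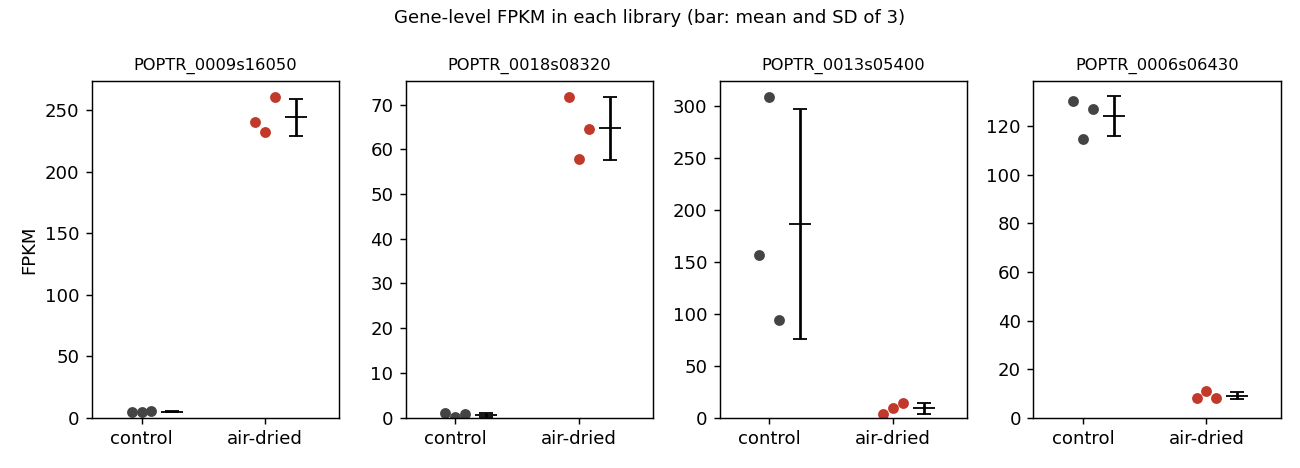
Gene-level FPKM in each library for the 4 genes given by accession, with the mean and SD of 3 libraries beside the points. The air-dried values of POPTR_0009s16050 lie between 232 and 261 FPKM and its control values between 4.46 and 5.58, while the control values of the 273 bp gene POPTR_0013s05400 spread from 93.6 to 309 FPKM.

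These differences were also estimated inside each of the 2 sets into which the libraries fell across the groups (set A, controls 1 and 2 with air-dried 1; set B, control 3 with air-dried 2 and air-dried 3). The log2 fold change of POPTR_0009s16050 was 5.43 within set A and 5.23 within set B, and that of POPTR_0018s08320 was 5.59 and 5.15. POPTR_0006s06430 changed by -3.74 and -3.62, and the short gene POPTR_0013s05400 by -5.70 and -2.91. With the set as a term, 1209 genes rose and 1547 fell, of which 1040 and 1392 were also called without it. Within set A 293 genes rose and 229 fell, and within set B 261 rose and 195 fell, from a limma model that pooled the spread. Each of these contrasts rests on a single library in 1 group (air-dried 1 in set A, control 3 in set B), which was assumed to vary like the others. The difference between the sets passed the threshold in 28 genes one way and 14 the other, and it rests on the same single libraries. Leaving out a single library brought the counts down to between 667 and 896 rising genes and between 812 and 1130 falling genes.

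Rising and falling genes differed in the length of genome they covered. Rising genes had a median span of 2605 bp and falling genes 3199 bp, a log2 ratio of -0.30 (permutation test, p = 1e-05, the smallest that 100000 permutations can give), while the median of all tested genes was 3525 bp. Among genes spanning at least 600 and under 1000 bp, 9.76% rose and 5.53% fell. At 2000 to under 4000 bp, 5.86% rose and 9.26% fell, and at 4000 bp or more 3.76% rose and 6.11% fell. The difference was not a steady trend: at 1000 to under 2000 bp the shares were highest and close to equal, with 10.64% higher and 10.28% lower, and at 300 to under 600 bp 3.11% rose and 3.39% fell. Genes spanning under 300 bp were seldom called, with 2.10% higher and 1.54% lower. These shares come from the fit without the library set, and the shortest classes followed the sets. At 300 to under 600 bp the median log2 change was -0.122, and 0.00675 with the set as a term. Under 300 bp it was -0.137, and 0.196 with the set as a term. The span log2 ratio with the set as a term was -0.43 (permutation p = 0.001). With changes of at least 4-fold the direction of the span difference turned, to a log2 ratio of 0.0948 (permutation p = 0.72).

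**Figure D3:**
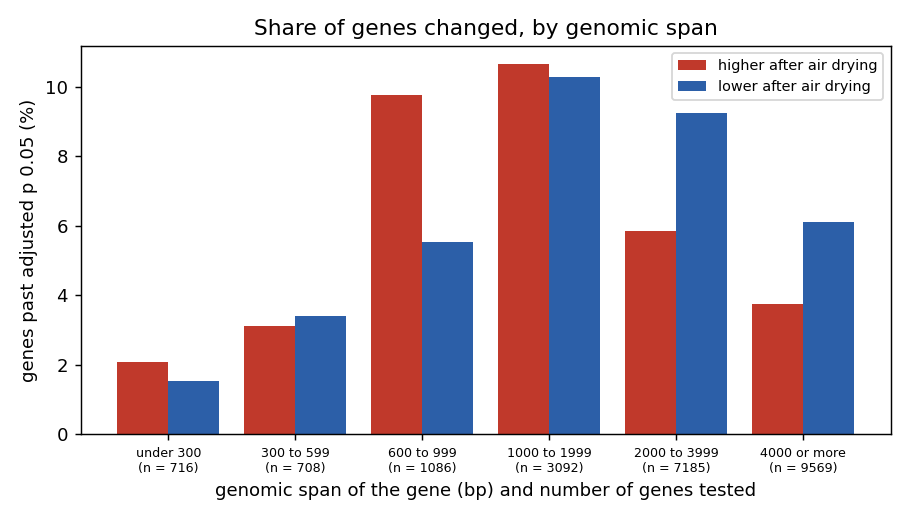
Percent of tested genes past the threshold in each class of genomic span (bp), with bars for genes higher (red) and lower (blue) after air drying and the number of tested genes under each class. Rising genes outnumber falling genes most at 600 to under 1000 bp (9.76% against 5.53%), the shares are close at 1000 to under 2000 bp (10.64% and 10.28%), and falling genes outnumber rising genes from 2000 bp on and slightly at 300 to under 600 bp (3.39% against 3.11%).

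Genes next to each other on a chromosome changed in the same direction more often than shuffled calls did. Among 21634 pairs of adjacent tested genes on chromosomes 1 to 19, 285 pairs were called in the same direction against 194.6 in the shuffles, a ratio of 1.47 (permutation p = 1e-05, the smallest possible here). Both genes rose in 110 of these pairs and both fell in 175. Opposite directions were found in 161 pairs against 184.5 in the shuffles (permutation p = 0.034), but this deficit was absent in pairs at least 1000 bp apart (152 against 153.3, permutation p = 0.48) and did not pass the threshold with the library set as a term (permutation p = 0.062). There were 26 runs of at least 3 adjacent genes with 1 direction, against a mean of 12.6 and a highest value of 32 in the shuffles. Some runs held genes whose spans overlap, among them a run of 4 on chromosome 8 (12997253 to 13031118). Runs were not counted without such overlaps. With the library set as a term the ratio of observed to shuffled pairs was 1.55.

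Of the 3 runs of 4 genes, the one with the largest mean change lay on chromosome 6 between 11398834 and 11450511 and was picked out after its values were seen. It held 4 plus-strand genes with 1 transcript each, all of which rose and all of which were also called with the library set as a term. The gene at 11398834 to 11399764 rose from 0.301 ± 0.141 FPKM to 16.6 ± 1.48 FPKM (SD, n = 3 each), a log2 fold change of 3.76 (SE 0.117). Its neighbour at 11403548 to 11404485 rose from 0.260 ± 0.221 FPKM to 15.4 ± 1.25 FPKM, a log2 fold change of 3.71 (SE 0.146). The gene at 11415819 to 11416430 rose from 3.18 ± 1.18 FPKM to 51.03 ± 5.70 FPKM, a log2 fold change of 3.67 (SE 0.221). The gene at 11449037 to 11450511 rose from 26.0 ± 0.640 FPKM to 56.3 ± 3.37 FPKM, a log2 fold change of 1.09 (SE 0.0710). The highest limma adjusted p of the 4 was 0.0006415. On chromosome 15, between 14181402 and 14283229, 4 minus-strand genes fell together, with log2 fold changes from -0.72 to -2.17, and 3 of them were called with the set as a term. Whether such neighbours are copies that share reads is not known here.

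**Figure D4:**
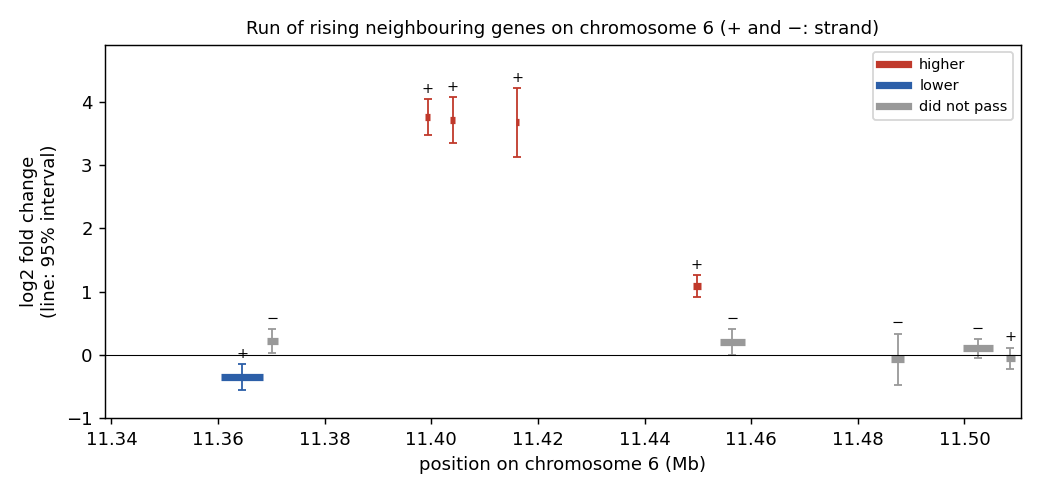
Tested genes around the run on chromosome 6, with position in Mb on the x axis and the log2 fold change, air-dried minus control, on the y axis; horizontal bars span each gene, vertical lines are 95% intervals and signs give the strand. The 4 rising genes (red) have log2 fold changes from 1.09 to 3.76, and 1 gene upstream of them was lower (blue).

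Across chromosomes, the share of falling genes stood apart on chromosome 10 alone. There 5.17% of tested genes fell against 7.75% on the other numbered chromosomes, an odds ratio of 0.649 (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.005695 over 38 tests). In Fisher's exact test the adjusted p passed the threshold neither with the library set as a term (odds ratio 0.726, p = 0.2132) nor with a mean of at least 5 FPKM (0.709, p = 0.3536).

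Genes without any known transcript were called less often than genes with one. The share called also depends on level and on the spread between libraries, which were not matched. Of 1439 such loci 62 (4.31%) were called, against 2854 (13.6%) of 20917 genes with a known transcript, an odds ratio of 0.285 (Fisher's exact test, p = 2.154e-30). Among loci spanning at least 300 bp the shares were 5.33% and 13.7% (Fisher's exact test, p = 1.165e-14). Of the called genes, 5 were listed at 0 in all 3 controls and 7 in all 3 air-dried libraries. A locus on chromosome 17 (798970 to 802712) was listed at 0 in the 3 controls and had FPKM of 72.5, 73.3 and 38.3 in the air-dried libraries. On chromosome 3 (3506938 to 3507882) a locus had 99.5, 199 and 389 FPKM in the controls and was listed at 0 in the air-dried libraries. Both loci were chosen after their values were seen, and each overlaps 1 other listed gene, so that reads of the overlapping genes may not have been told apart.

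Single transcripts gave fewer calls than gene sums. Of 41577 transcripts tested, 362 rose and 358 fell, and with the library set as a term 328 rose and 260 fell. The split of the libraries into sets A and B called 1428 transcripts, against 720 for the split into controls and air-dried. Known transcripts were called in 3.19% of cases (299 higher, 291 lower) and assembled transcripts in 0.564% (63 higher, 67 lower; Fisher's exact test, p = 1.769e-96). Of 16457 genes with more than 1 transcript, 10262 (62.4%) had the same leading transcript in all 6 libraries. In 56 genes the controls shared 1 leading transcript and the air-dried libraries shared another, and 8 of these were called as genes. The count of 56 fell to 6 with a lead of 10 percentage points in every library and rose to between 109 and 236 with a library left out. The split of the libraries into sets A and B gave 430 such genes, and the remaining splits gave 37 to 78.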

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

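Pseudocount, filter, scaling, block, trend, single-transcript and left-out-library settings of the gene counts were planned; the library set as a term, genes spanning at least 300 bp, sums of known transcripts and all settings for spans, neighbours, chromosome 10 and leading transcripts were chosen after the data were seen. The 4 genes given by accession kept their direction and their call in 67 of 67 alternatives, with a highest limma adjusted p of 0.03468. Testing single transcripts called 362 higher and 358 lower, and sums of known transcripts gave 667 genes higher and 754 lower, with 2 genes called in the opposite direction; the cause was not tested. With each library left out, 667 to 896 genes were higher and 812 to 1130 lower, from fewer samples. Higher genes moved by over 1.5 times without control 1 (680), control 2 (667), air-dried 1 (782), air-dried 2 (768) or air-dried 3 (749), and lower genes without control 1 (965), control 2 (812), control 3 (1105), air-dried 1 (1102) or air-dried 2 (954). Genes changed at least 2-fold ranged from 469 (mean of at least 5 FPKM, fewer genes tested) to 971 (pseudocount of 0.1). Pairing by replicate number was not established. Deviations of same-numbered libraries correlated at 0.187, -0.0961 and 0.292. With other air-dried libraries these controls reached at most -0.0127, 0.16 and 0.11. Numbers 1 and 3 each lie in 1 library set and number 2 in both, so pairing cannot be told from the sets. With the replicate block 924 genes were higher and 1197 lower, and 673 changed at least 2-fold.

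The neighbour ratio stayed between 1.37 and 1.86 in 20 of 20 alternatives, while the deficit of pairs in opposite directions was lost under several of them (permutation p = 0.12 with the replicate block and 0.5 for pairs on the same strand). The span ratio kept its direction in 19, and reversed to 0.0948 among genes changed at least 4-fold (permutation p = 0.72), where 87 and 36 genes were compared; without single libraries it ranged from -0.58 to -0.24. The chromosome 10 odds ratio lost its call in Fisher's exact test with no filter (0.703, p = 0.05462), a mean of at least 5 FPKM (0.709, p = 0.3536), the replicate block (0.681, p = 0.1465), the set as a term (0.726, p = 0.2132) and known transcripts (0.708, p = 0.4885); the cause was not tested, and without single libraries it ranged from 0.529 to 0.624. Another leading transcript was found in 36 genes at a gene mean of at least 5 FPKM, where fewer genes were compared, in 6 with a lead of 10 percentage points, and in 109 to 236 with a library left out (148 and 109 without controls 1 and 2, 236 without control 3, 202, 147 and 161 without air-dried 1, 2 and 3). Gene list tests were not run because no names were given, and count-based tests were not run because the values are FPKM. Absolute depth is unknown, so the precision of low values cannot be stated.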

Other observations

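The tests of neighbouring genes and of leading transcripts over other splits were set before their results were seen; the tests of the library sets, of the falls and of the other splits for gene counts were chosen only after the results were seen.

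Larger responses were separated from small ones by their intervals. Leaving aside genes listed at 0 in a whole group, 217 rising genes had a lower 95% bound above a log2 change of 1 and 57 had one above 2. Among falling genes 136 had an upper bound below -1 and 13 had one below -2. On chromosome 2, between 8930778 and 8949849, 3 adjacent genes rose with log2 fold changes from 0.55 to 2.97, from 2.03 to 8.69 FPKM in the controls to 8.07 to 22.6 FPKM after drying. On chromosome 18, between 11761812 and 11775629, 3 plus-strand genes rose with log2 fold changes from 1.36 to 1.52. These regions were chosen after their values were seen, and all 3 genes of each were also called with the library set as a term.

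The libraries fell into 2 sets that crossed the groups, controls 1 and 2 with air-dried 1 against control 3 with air-dried 2 and air-dried 3. Rank correlations of transcripts were 0.817 to 0.863 within a set and 0.733 to 0.773 across sets. Genes spanning under 300 bp had a median log2 difference of -1.029 (set B minus set A, 95% bootstrap interval -1.12 to -0.93, 716 genes), against 0.027 in genes of 2000 bp or more, as a difference in fragment length, entering FPKM through the effective length of short transcripts, would give. The interval comes from 1000 resamplings of genes, so it measures the spread between genes in these 6 libraries and not the spread between libraries. The relative depths of the sets overlapped (gap of -0.059), but only through air-dried 3, without which set B lay above set A by 0.0477. On that test a depth difference stays open. The correlations cannot settle it, because the sets were drawn from them. Depth ratios were also less sharp across the sets, where 11.5% to 20.7% of low genes lay within 0.03 log2 of the commonest ratio. Within a set this share was 22.3% to 28.8%. Control 2 and air-dried 2 were close in relative depth (1.016 and 1.064) and correlated at 0.733 across the sets. Control 3 and air-dried 3 were far apart (1.334 and 0.957) and correlated at 0.863 within set B. No pair across the sets came above 0.773, which follows from how the sets were drawn. Fragment length is a candidate explanation only, because the labels give neither fragment sizes nor batches, and no biological explanation of the sets was tested.

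Falls of at least 2-fold within about 10 minutes were seen in 332 genes. With the set as a term 97.9% of them were still called lower, and their median log2 change went from -1.27 to -1.26. These genes were picked by a fit without the set, in which a difference between the sets widens the spread within each group. Genes that follow the sets were therefore unlikely to be picked, so the high share does not test the sets as a cause. Short loci do not account for most of the falls: 11 of these genes (3.31%) span under 300 bp, beside 716 of the 22356 tested genes. Yet all 11 called falling genes of that span are among these falls. They include the 273 bp gene POPTR_0013s05400, which had the largest estimated fall among called genes not listed at 0. If transcription had stopped alone, the gene with the lowest upper 95% bound among those not listed at 0 (POPTR_0006s06430, bound of -3.34, not the largest estimated fall) would need a half-life of at most 2.99 minutes; 2 genes had a bound below -5, and both were listed at 0 in all air-dried libraries, where a fold cannot be given. A stop of transcription, faster decay, or a treatment that took longer than stated by the time of harvest cannot be told apart, because no harvest time or decay rate was measured, and lifting and washing the plants may have added to the response.

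Neighbouring genes changed together more often than shuffled calls. Overlapping gene models as the whole cause are argued against. Pairs at least 1000 bp apart with different strand marks were still called together 1.372 times as often as in the shuffles (112 pairs against 81.7, permutation p = 0.0007). A locus without a strand mark counted as different from either strand, so split gene models stay partly open. The library sets are argued against too, since the ratio was 1.547 with the set as a term. Tandem copies that share reads, or shared regulation of neighbours as a response to drying, may contribute; without sequences neither was tested.

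With 3 libraries against 3 there are 10 splits, so no share under 0.1 can be reached. The other splits mix controls with air-dried libraries, so a real group difference widens their spread and lowers their counts. Their counts therefore need not be those to be had without a group difference. For higher genes, 1 of the 10 splits, the real one, gave a count as large (1253 against at most 103 in either direction elsewhere). For lower genes it was again 1 of 10 (1663 against at most 103), and for genes changed at least 2-fold 1 of 10 (688 against at most 112). The highest of the other splits was the library sets in each case. For genes with another leading transcript 4 of the 10 splits gave as many or more (56 against 430 for the library sets). Chance is not excluded there, nor is it excluded for the gene counts by a share of 0.1. For single transcripts the split into sets called 1428 against 720 for the real one. The sets were found from these same transcript values, so neither this count nor the 430 above is separate support for them. With the set as a term 328 transcripts were higher and 260 lower after drying.

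Loci 1 bp longer than a read of 100 bp had FPKM that were whole multiples of the smallest value in each library, within a tolerance of 0.01. The smallest value was 42470, 45950 and 19680 in the controls and 45630, 51790 and 44720 in the air-dried libraries, and between 5 and 8 of the 205 such loci were above 0 in a library.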
